A study of Mus musculus with 24 samples.

How the data were processed

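AGO2 HITS-CLIP libraries were made from activated CD4+ T cells of 12 wild-type and 12 miR-155 knockout mice or cultures, each labelled a biological replicate, with 6 libraries of each genotype per 3' linker. Per the labels' protocols, lysates were partly digested with RNase, AGO2 complexes were immunoprecipitated, and the RNA of size-selected complexes was ligated to linkers, reverse transcribed and amplified. The primer carried a degenerate barcode that can mark duplicate molecules; whether duplicates were collapsed is not given in the sources used here. Per the submitters' processing notes, Bowtie 0.12.7 and the mm9 genome were used. The peak caller, the scaling of reads and the test behind the p-values are not given in the sources used here.

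The authors' deposited table holds 14634 peaks, all labelled as 3' UTR by the authors, each with a transcript, a gene symbol, start and end counted from the first nucleotide of the 3' UTR, and the sequence. Per the file headers, its deposited log2 values are the reads of each genotype and their ratio, wild type over knockout, and its deposited p-value is for differential binding. The log2 ratio equalled the difference of the genotype columns to within 6e-05. After taking 1 off, the commonest value below 1 was 0.976 in wild type and 0.718 in the knockout. Of the values under 3, 217 of 1573 and 238 of 1653 were whole multiples of these (tolerance 0.002), so no single step holds. With 0.5 taken off instead, 35 of 1212 and 15 of 1272 were multiples of the commonest value. The columns were read as log2(1 + scaled reads) pooled over the libraries of a genotype, and the scaled reads were computed by reversing this. The pseudocount of 1 understates the change of peaks with few reads.

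The table pools libraries, so a test per peak across libraries, which had been planned with a term for the linker, could not be made. The authors' p-values were adjusted by the Benjamini-Hochberg method over all peaks, with a threshold of 0.05, and a positive ratio was read as lower in the knockout. The deposited p-values were below 0.05 for 4.20% of peaks and above 0.95 for 9.03%, so their distribution is not uniform. What spread between libraries they reflect is unknown. The depth of the libraries is unknown too, so the planned counting intervals were not computed, and a genotype without reads is given as listed at 0, with no fold.

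Each peak sequence was searched for matches to miR-155: 8mer, 7mer-m8, 7mer-A1, 6mer, offset 6mer and 6mer-A1, each peak counted in its longest class. A further 15 microRNA families were searched for 7-nt and 8-nt sites. The deposited sequence extended 6 nt beyond the peak on each side in 14608 peaks. Site presence among lowered peaks was compared by 2-sided Fisher's exact tests with the 7097 other peaks holding at least as many scaled reads as the least-read called peak (17.6). Medians of peak sets were set against 10000 random sets matched in 20 bins of reads. Site classes were compared by permutation tests with 100000 resamples. Gene lists were tested by Fisher's exact test on genes with at least 1 peak of 17.6 or more scaled reads, for lists of 5 or more peaks, adjusted over 14 lists. They covered known miR-155 targets, T cell receptor and costimulation, cytokine receptors and JAK-STAT, helper T cell transcription factors, NF-kB, PI3K-AKT-mTOR, cell cycle, apoptosis, chromatin regulators, the microRNA pathway, TGF-beta and SMAD, ubiquitin ligases, markers of B cells, myeloid cells, CD8 and NK cells, and erythroid cells and platelets, and the miR-155 host gene.

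Genome positions come from exact matches of peak sequences to GENCODE M21 transcripts and are on GRCm38, not on the authors' mm9; 96.99% of sequences matched a transcript of the named gene, and those without a match have no position. Of 13826 peaks placed on transcripts with an annotated coding region, 13680 lay in annotated 3' UTRs. The lowered peak 2 of Nf1 lay in other exon sequence of that annotation. The lowered peak 1 of Wnk1 was placed on a transcript without an annotated coding region. The genes named were set before the data were examined: the 15 lowered peaks (1 per gene) and up to 10 raised peaks with the smallest p, 12 known targets, and up to 4 members of each list; a few of these are not reported here. The rule for pooled values added the 15 largest and the 10 lowest ratios (1 peak per gene) among peaks of at least 20 scaled reads. Other genes named, such as those with the most reads, with 2 lowered peaks or without a seed match, were chosen after their values were seen. Alternatives tried were adjusted p thresholds of 0.01 and 0.1, a minimum of 10 scaled reads, no pseudocount, other site definitions, a region widened by 20 nt, and, added after seeing the data, a Bonferroni adjustment, peaks with reads in both genotypes with and without the pseudocount, centred ratios, the region without flanks, and site classes over peaks with reads in both genotypes.

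Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data over the 14634 peaks of this comparison. Sets of 200 peaks shifted by 0.5 or 1 log2 units lay above the 95% range of matched sets in 20 of 20 runs each, and unshifted sets lay outside the 95% range in 2 of 20. The adjustment recovered 100% of 200 changed peaks, with 5.08% of the called peaks unchanged. A planted 6-mer ranked first in 20 of 20 runs.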

Results

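Argonaute 2 (AGO2), the protein that carries microRNAs to their target messenger RNAs, was crosslinked to RNA and immunoprecipitated from CD4+ T cells of C57BL/6 mice, and the bound RNA was sequenced (HITS-CLIP). The cells came from spleen and lymph nodes and had been activated in culture with antibodies to CD3 and CD28 (1 µg/mL) and IL-2 (20 U/mL) for 4 days. The 24 libraries comprised 12 from wild-type mice and 12 from mice lacking miR-155, a microRNA induced when lymphocytes are activated. In each genotype 6 libraries carried 1 of the 3' linkers and 6 the other. Among the first 6 replicate numbers all knockout libraries carried 1 linker and all wild-type libraries the other, and the last 6 were the reverse. Within each of these sets linker and genotype cannot be told apart, and the pooled reads do not separate the sets. The authors' deposited table gave pooled reads per genotype for 14634 AGO2 peaks that it assigns to the 3' untranslated regions (3' UTRs) of 4165 genes. The comparison of the genotypes asks which AGO2 contacts depend on miR-155 and what sequence they contain.

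All read numbers below are the authors' pooled and scaled reads, with no value per library and therefore no replicate error. They summed to 371088 in wild type and 374126 in the knockout over all peaks. A peak held a median of 17.0 scaled reads in both genotypes together (quartiles 7.90 and 40.9). No wild-type reads were listed for 1151 peaks and no knockout reads for 2426. The depth of single libraries is unknown, so no counting interval is given.

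After Vmp1, with 5.38% of all reads, most of them over the gene of miR-21, the most heavily occupied 3' UTRs included those of regulators of T cell activation. Btg2, which restrains proliferation, held 5739 scaled reads in wild type and 7094 in the knockout over 23 peaks. Hif1a, the oxygen-regulated transcription factor, held 4285 and 4747 over 24 peaks. Dusp2, a phosphatase of MAP kinases, held 3619 and 4583, and the activation marker Cd69 held 3320 and 3482. The cell cycle inhibitor Cdkn1b held 3218 and 3326, and Il2ra, the alpha chain of the IL-2 receptor, held 1934 and 3293. The ubiquitin ligase gene Cblb held 1929 and 2305, and the costimulatory receptor gene Cd28 held 1639 and 2111. Trp53inp1, a p53-induced stress gene, had the most peaks of any gene, 43, and Irf4, a transcription factor of effector T cells, had 34.

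AGO2 lost contact with a small set of 3' UTR positions when miR-155 was absent. At an adjusted p below 0.05, 84 peaks in 79 genes were lower in the knockout and 4 peaks in 4 genes were higher. For 43 of the 84 lowered peaks the knockout was listed at 0 reads. The affected genes included Hat1, which acetylates newly made histones, Rcor1, a scaffold of a corepressor complex, Hif1a, the AP-1 subunit gene Fosl2, and Tnfsf9, the ligand of the costimulatory receptor 4-1BB.

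The smallest p-value in the authors' deposited table belonged to peak 2 of Hat1, with 147 scaled reads in wild type and 5.78 in the knockout (log2 ratio 4.45, p = 8.05e-54, Benjamini-Hochberg adjusted p = 1.18e-49). This peak starts 138 nt into the 3' UTR (transcript NM_026115.4), and its sequence matched chromosome 2, 71441467 to 71441514, of GRCm38, in exon 11 of 11. Peak 18 of Rcor1 held 105.9 reads in wild type and was listed at 0 in the knockout (chromosome 12, 111115704 to 111115755; adjusted p = 1.87e-36). A further peak of Rcor1, peak 7, went from 84.5 scaled reads to 0. Peak 3 of Dusp11, which encodes an RNA phosphatase, held 133 and 0 reads (chromosome 6; adjusted p = 5.66e-30). Peak 4 of Hif1a fell from 146 to 8.85 reads (chromosome 12, 73945885 to 73945923; log2 ratio 3.90 in the authors' deposited table, adjusted p = 4.17e-26). Peak 17 of Ash1l, a histone methyltransferase gene, held 111 reads in wild type and 0 in the knockout (adjusted p = 1.68e-25). Peak 7 of Fosl2 held 166 reads in wild type and was listed at 0 in the knockout (chromosome 5, 32156916 to 32156958).

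The next 9 genes by p follow in that order. Peak 8 of Mobkl3 held 103 reads in wild type and 0 in the knockout. Lpin1, a phosphatidate phosphatase of lipid synthesis, had 656 reads at peak 5 in wild type and 43.7 in the knockout. P2ry10, a G protein-coupled receptor gene of lymphocytes, had 196 and 2.87 at peak 5. Lmbrd1, which serves the export of vitamin B12 from lysosomes, had 112 and 2.57, and the zinc finger gene Zfp518a had 77.7 and 1.5. The Tnfsf9 peak fell from 508 to 39.1 reads (log2 ratio 3.67 in the authors' deposited table, adjusted p = 6.61e-14). Rcn2, a calcium-binding protein of the endoplasmic reticulum, had 111 reads and 0. Wnk1, a kinase that controls ion transport, had 105 and 2.23. Irf2bp2, a transcriptional co-repressor gene, had 77.6 and 0 (adjusted p = 2.49e-11).

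The 15 peaks with the largest log2 ratios among those with at least 20 scaled reads, taking 1 peak per gene, were all among the lowered peaks, and 13 of them held a 7-nt or 8-nt miR-155 site. As 13 of the 15 were listed at 0 in the knockout, this order mostly follows their wild-type reads. Besides genes already named, they included Mpeg1, a perforin-like gene, with 122 reads in wild type, and Pank3, an enzyme of coenzyme A synthesis, with 121; both were listed at 0 in the knockout. They also included Aff4, a transcription elongation factor gene, with 121 reads and 1.04.

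**Figure D1:**
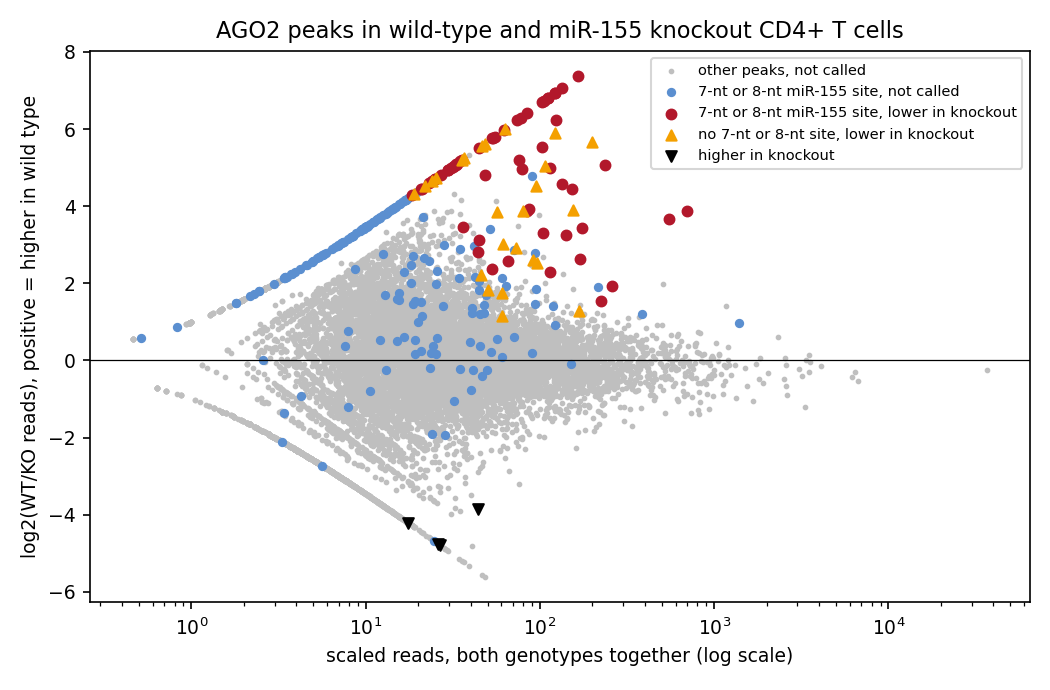
Each point is an AGO2 peak; the horizontal axis gives its scaled reads in both genotypes together on a log scale, and the vertical axis the log2 ratio of wild-type to knockout reads. The 84 peaks lower in the knockout (red circles with a 7-nt or 8-nt miR-155 site, orange triangles without) lie above 0, the 4 higher peaks (black) lie below it, and the rising upper edge holds peaks listed at 0 in the knockout.

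Several genes long studied as miR-155 targets lost a peak, and others did not. Of the 12 known targets chosen before the data were examined, 9 had peaks in the authors' deposited table and 5 had a lowered one. Jarid2, a cofactor of Polycomb repressive complex PRC2, fell from 129 to 4.46 scaled reads at peak 2 (chromosome 13, 44920073 to 44920120; adjusted p = 2.22e-10). Maf, a transcription factor of helper T cells, had 62.9 reads in wild type and 0 in the knockout (chromosome 8; adjusted p = 1.30e-05). Bach1, a heme-regulated repressor gene, had 53.9 and 0 (chromosome 16; adjusted p = 9.07e-05). Inpp5d, which encodes the inositol phosphatase SHIP1, had 31.0 and 0 (chromosome 1; adjusted p = 0.000225). Cebpb, a transcription factor gene of myeloid cells and cytokine responses, kept more reads in the knockout, 56.9 against 167 (chromosome 2; adjusted p = 0.0111).

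The other 4 known targets in the table had no called peak. Peak 3 of Tab2, an adaptor of NF-kB signalling, held 48.3 scaled reads in wild type and 3.65 in the knockout, with p = 0.00224 in the authors' deposited table and an adjusted p of 0.219. Trp53inp1 had 925 and 471 reads at its 8-nt site (adjusted p = 0.377). The peak of Ets1 with its smallest p had 30.2 and 2.17 reads and no seed match (adjusted p = 0.742). Socs1, an inhibitor of cytokine signalling, had 2.77 and 3.0 reads at the peak with its smallest p. Its peak 3 held 211 reads in both genotypes together, with a log2 ratio of 0.02 in the authors' deposited table and no seed match. No peak is listed for Ikbke, Spi1 and Ctla4.

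**Figure D2:**
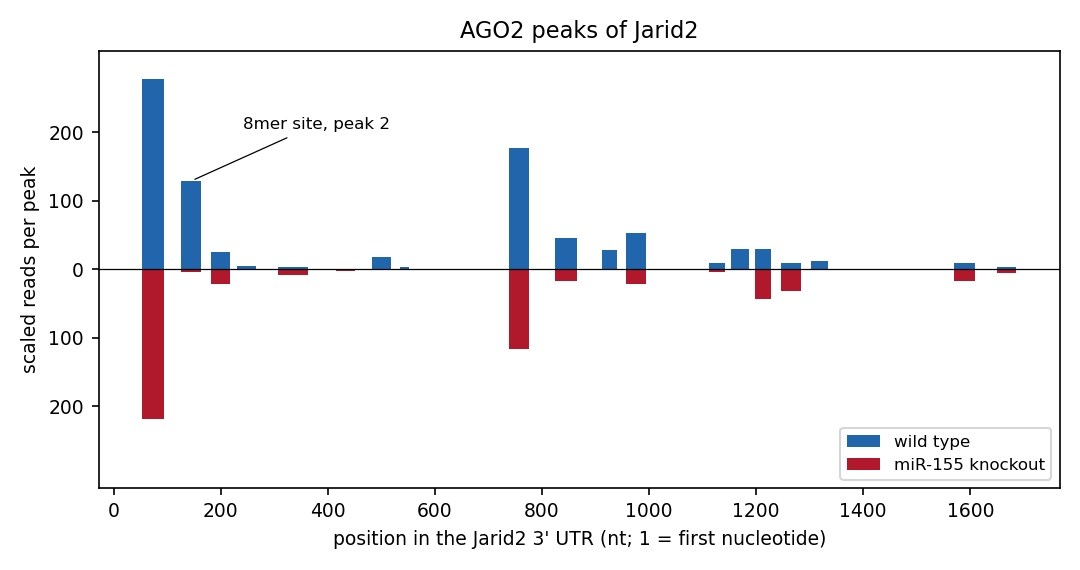
Bars show scaled reads of the 19 AGO2 peaks of Jarid2 along its 3' UTR (horizontal axis, nt), upward for wild type (blue) and downward for the knockout (red); bar width is the peak length. Peak 2, with an 8-nt miR-155 site, fell from 129 to 4.46 reads, while peak 1 beside it held 277 and 218.

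Few peaks were higher without miR-155. Kpna4, an importin that carries proteins into the nucleus, had 42.1 scaled reads in the knockout and 1.98 in wild type at peak 8 (chromosome 3, 69068509 to 69068564; adjusted p = 2.17e-06). Tnfrsf8, the activation receptor CD30, had 26.7 in the knockout and was listed at 0 in wild type (adjusted p = 0.00455). Tmem170b had 17.6 and 0 (adjusted p = 0.0177), and C030046E11Rik had 26.1 and 0 (adjusted p = 0.0394). None of these 4 peaks held a match to the miR-155 seed. Of the 10 peaks with the most negative log2 ratios, 1 per gene and again with at least 20 scaled reads, all were listed at 0 in wild type. They included Mcf2l with 48.3 reads in the knockout and 0 in wild type and the cytokine gene Il21 with 35.6 and 0, and none passed the threshold. Only 39 lowered peaks and 1 higher peak remained when peaks without reads in a genotype were left out of the adjustment. At an unadjusted p below 0.05, 398 peaks were higher in wild type and 217 in the knockout in the authors' deposited table.

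The lowered peaks were sites of miR-155 in most cases. A match of 7 or 8 nt to the miR-155 seed was present in 59 of the 84 lowered peaks (70.2%, exact 95% interval 59.3 to 79.7%), among them those of Hat1, Rcor1, Fosl2, Jarid2 and Inpp5d. The same match was present in 84 of the 7097 other peaks with as many reads as the least-read called peak (1.18%; 2-sided Fisher's exact test, p = 5.19e-86, adjusted over 16 families 8.31e-85). Counting 6-nt matches too, 67 of 84 lowered peaks held a site, including those of Maf, P2ry10, Aff4 and Icos. The 6-mer GCATTA, the complement of the seed, had the smallest p of 4088 6-mers tested between lowered and other peaks.

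Peaks with a miR-155 site lost AGO2 reads as a group, beyond those called singly. The 265 peaks with a 7-nt or 8-nt match had a median log2 ratio of 3.16 (quartiles 1.79 and 4.17). Over the 107 of them with reads in both genotypes it was 1.58, and 1.82 with no pseudocount. These 107 leave out every site peak listed at 0 in a genotype, so peaks without any knockout reads are missing from them. The ratio of a peak listed at 0 depends on the pseudocount and its other reads. Random sets of peaks matched on reads had a median of 0.15, with 95% of 10000 sets between -0.01 and 0.32. Of the 143 site peaks with at least 17.6 scaled reads, as many as the least-read called peak, 132 were higher in wild type. Il7r, the IL-7 receptor gene, had 170 reads in wild type and 44.4 in the knockout at an 8-nt site, yet an adjusted p of 0.430. A second 8-nt site in Jarid2, peak 11, had 27.6 reads in wild type and 0 in the knockout, with an adjusted p of 1.00. These sets describe the pooled libraries, since peaks are not independent replicates.

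The loss was larger for 7-nt and 8-nt matches than for shorter ones. Among peaks with at least 17.6 scaled reads, the median log2 ratio was 4.68 for 37 peaks with an 8mer, such as those of Fosl2, Ash1l and Jarid2. It was 2.96 for 47 peaks with a 7mer-m8, such as Rcor1 and Dusp11, and 2.58 for 59 with a 7mer-A1, such as Hat1 and Lpin1. It was 0.77 for 56 peaks with a 6mer, such as Maf and P2ry10. The 8mer peaks had higher ratios than the 7mer-m8 peaks (2-sided permutation test across peaks, p = 0.0155, adjusted over 9 comparisons 0.0232) and the 7mer-A1 peaks (adjusted p = 0.00583). Both 7mer classes exceeded the 6mer class (adjusted p = 0.00348 and 0.00583), and their difference from each other, 0.38, did not pass the test (adjusted p = 0.602). Many of these peaks are listed at 0 in the knockout. Among those with reads in both genotypes the medians were 2.20 for 14 8mer, 1.81 for 32 7mer-m8, 1.85 for 43 7mer-A1 and 0.69 for 47 6mer peaks. There the difference of the 8mer class from either 7mer class did not pass (permutation tests, adjusted over 5 comparisons, p = 0.808 each). Both 7mer classes exceeded the 6mer class (adjusted p = 0.0045 each). This restriction drops peaks by their result: it kept 14 of 37 8mer, 32 of 47 7mer-m8 and 43 of 59 7mer-A1 peaks. It therefore cannot tell whether 8mer sites lose more than 7mer sites. Shorter matches showed smaller shifts. The 112 peaks with a 6mer-A1, Hif1a and Wnk1 among them, had a median of 0.20 (adjusted p = 0.0273 against matched peaks without a match), and the 89 with an offset 6mer had 0.01 (adjusted p = 0.842).

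**Figure D3:**
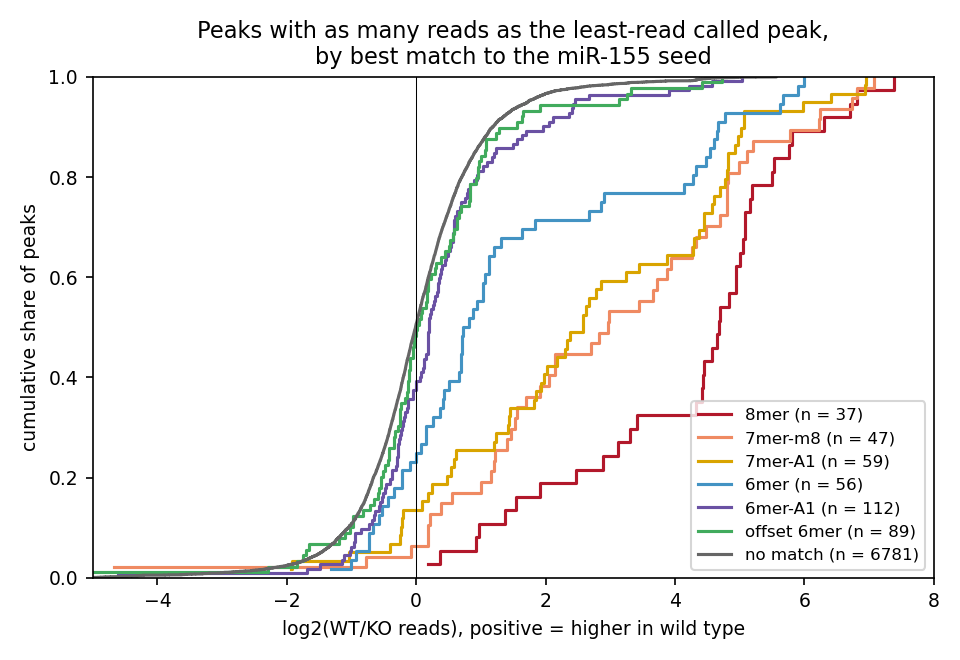
Lines give the cumulative share of peaks (vertical axis) up to each log2 ratio of wild-type to knockout reads (horizontal axis), for peaks with at least 17.6 scaled reads, by their longest match to the miR-155 seed. The 8mer line lies farthest to the right, with a median of 4.68, followed by the 7mer classes and the 6mer, while peaks with no match centre on -0.01.

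Not every site peak lost reads. Among the 143 site peaks, 11 had a log2 ratio at or below 0 in the authors' deposited table. Zfp568 had 24.6 scaled reads in the knockout and was listed at 0 in wild type. Map3k8, a kinase of inflammatory signalling, had 23.2 in the knockout and 5.37 in wild type, and Chd7, a chromatin remodeller, had 25.5 and 14.5. None of the 11 passed the threshold in either direction.

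A minority of lowered peaks lacked these matches. The peak of Ddx42, an RNA helicase gene, held an offset 6mer, and 16 held neither a 6mer nor an offset 6mer. Besides Hif1a and Wnk1, which held the weaker 6mer-A1, they lay in Arhgap18 (78.6 scaled reads in wild type, 12.2 in the knockout), Unc119b (36.8 and 0) and Fbxo11, a ubiquitin ligase subunit gene (55.5 and 5.93). They also lay in Gimap3, a GTPase gene of lymphocytes (82.7 and 13.6), Zc3h11a (75.7 and 4.27), the pseudokinase gene Trib1 (35.8 and 0) and the amino acid transporter gene Slc38a2 (53.9 and 2.79). The activation marker Cd69 had the smallest log2 ratio of any lowered peak, 1.16 in the authors' deposited table (42.1 and 18.3 reads; adjusted p = 0.0267). Gas2l3, Hiat1, Rasa2, Gng12, Ttc39b and the lamin gene Lmnb1 had 1 such peak each.

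Sites of any 1 other microRNA family were rare both among lowered peaks and among other peaks. For each of 15 other families of T cells, including let-7, miR-17, miR-142, miR-15/16 and miR-21, 0 to 2 lowered peaks held a 7-nt or 8-nt site (at most 2.38%). Among the other peaks with at least 17.6 scaled reads the shares were 0.56 to 5.89%. No such family differed by Fisher's exact test (smallest p adjusted over 16 families, 0.310). The medians of 13 of these families did not differ from matched random sets after adjustment over the 16 families. Peaks with a miR-181 site leaned the other way, with a median log2 ratio of -0.11 against 0.19 for random sets (adjusted p = 0.0048). Those with a miR-29 site also did, -0.04 against 0.14 (adjusted p = 0.0373). The miR-181 median lay inside its matched range among peaks with at least 10 scaled reads (-0.07; range -0.08 to 0.24). The miR-29 median did so among peaks with reads in both genotypes (-0.06; range -0.07 to 0.17). For miR-155 the adjusted p was 0.0032, from the smallest p that 10000 random sets can give.

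**Figure D4:**
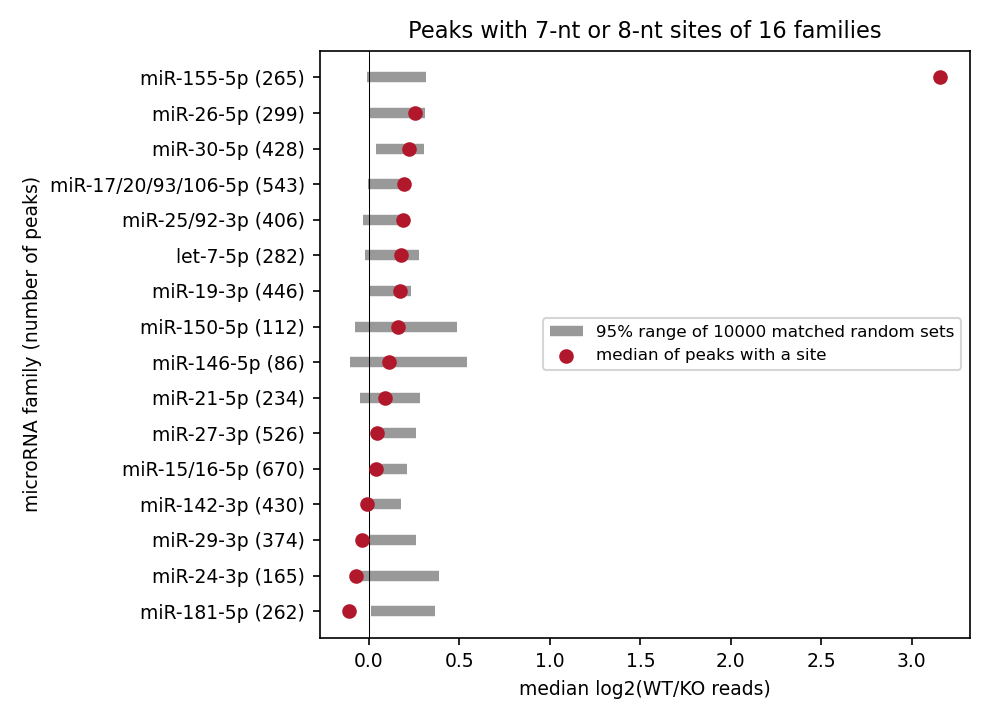
Points give the median log2 ratio of wild-type to knockout reads (horizontal axis) of peaks with a 7-nt or 8-nt site of each of 16 microRNA families, with the number of peaks in brackets; grey bars span 95% of 10000 random sets of peaks matched on reads. The miR-155 point, at 3.16, stands far to the right of its bar, and the other 15 lie between -0.11 and 0.26.

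Known miR-155 targets as a list had lowered peaks more often than other genes. Of its 40 genes 29 had peaks, and 12 of the 25 with a peak of at least 17.6 scaled reads had a lowered one, against 67 of 2712 other genes (Fisher's exact test, adjusted over 14 lists, p = 7.68e-12). The 12 were Rcor1, Hif1a, Fosl2, Jarid2, Gpm6b, Rheb, Maf, Bach1, Inpp5d, Cebpb, Peli1 and Picalm. Adjusted over the list alone, 15 peaks were lowered and 0 raised, against 13 and 0 over all peaks. The median log2 ratio of its 285 peaks was 0.60, against 0.11 in matched sets. The list was compiled from general knowledge of the field, so it is not certain to be independent of this study.

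T cell signalling genes lost single peaks. In the list of T cell receptor and costimulation genes, 3 of 20 had a lowered peak (adjusted p = 0.0648). They included Icos, a costimulatory receptor gene (64.8 scaled reads in wild type and 7.77 in the knockout), and Cd69. The PI3K-AKT-mTOR list had 3 of 17, with an adjusted p of 0.0549. These were Rheb, the GTPase that activates mTORC1 (128 and 12.6), Rps6ka3, a kinase downstream of ERK (79.8 and 4.51), and Inpp5d. Rheb and Inpp5d are also on the list of known miR-155 targets, and without those targets 1 of 15 genes had a lowered peak. In the NF-kB list 1 of 14 genes had a lowered peak, Peli1, a ubiquitin ligase gene (147 and 23.1; list adjusted p = 0.590). The list of cytokine receptors and JAK-STAT genes had none among 31 genes. In this list Ifngr2, a chain of the interferon gamma receptor, had 4.47 and 39.5 reads (adjusted p = 0.131). The median of its 207 peaks was -0.09, against 0.14 in matched sets (adjusted p = 0.0504). With known miR-155 targets left out, the medians of 3 lists lay toward the knockout. That of cytokine receptors was -0.14 against 0.15 (adjusted over 13 lists, p = 0.0234). Helper T cell transcription factors had -0.20 against 0.11 (0.0052), and -0.04 against 0.11 as a full list (adjusted over 14 lists, p = 0.169). Apoptosis genes had -0.10 against 0.17 (0.026), but 0.21 against 0.17 as a full list (0.760), a change of direction from leaving out Trp53inp1 with its 43 peaks. The matched sets drew single peaks without regard to gene. The reduced lists held 180 peaks of 29 cytokine receptor genes, 248 of 25 transcription factor genes and 174 of 18 apoptosis genes. Peaks of 1 gene are not independent, so these p-values may be too small.

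Single regulators of transcription and chromatin lost peaks too, though none of the lists in this paragraph passed the threshold. Among 28 helper T cell transcription factors with a peak of at least 17.6 scaled reads, 3 had a lowered peak (list adjusted p = 0.115). They were Maf, Bach1 and Ahr, the aryl hydrocarbon receptor gene (23.2 scaled reads and 0). Irf4 in this list had a peak with 0.463 reads in wild type and 40.1 in the knockout that did not pass (adjusted p = 0.288). Chromatin regulators had 3 of 29 genes with a lowered peak (adjusted p = 0.115): Rcor1, Jarid2 and Mll5, a SET domain gene (231 and 5.93). With known miR-155 targets left out, 1 of 24 helper T cell transcription factors and 1 of 26 chromatin regulators had a lowered peak. Ubiquitin ligases of T cells had 3 of 15 (adjusted p = 0.0549): Rc3h2, the RNA-binding protein Roquin-2 (123 and 0.634), Fbxo11 and Peli1. Without known miR-155 targets it was 2 of 13 (Fisher's exact test, adjusted over 13 lists, p = 0.339). Cell cycle genes had 2 of 27 (adjusted p = 0.364): E2f2, a transcription factor of S phase entry (53.2 and 0), and Mcm2, a subunit of the replicative helicase (55.0 and 0), both at 8-nt sites.

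Other lists held few or no lowered peaks. Apoptosis genes had 0 of 17 genes, the microRNA pathway 0 of 12, and TGF-beta and SMAD signalling 0 of 14 (list adjusted p = 1.00 each). At an unadjusted p below 0.05 these 3 lists had 4, 5 and 2 peaks higher in wild type and 5, 1 and 1 higher in the knockout in the authors' deposited table. Examples are Casp6, an effector caspase gene (0 scaled reads in wild type and 29.5 in the knockout; adjusted p = 0.386), and Tnrc6a, the AGO partner GW182 (24.5 and 0; adjusted p = 0.0610). Markers of other cells were scarce among the genes listed. B cell markers had 4 peaks in 4 genes, CD8 and NK cell markers 11 peaks in 4 genes, and erythroid and platelet markers 12 peaks, all in Tfrc, which dividing T cells also express; the lists of CD8 and NK and of erythroid markers had an adjusted p of 1.00 each, and the B cell list had too few peaks to be tested. Of these, none was called over all peaks, while Cr2 passed when adjusted over the B cell list alone (0 reads in wild type, 11.6 in the knockout). Myeloid markers had 2 peaks, both in Cebpb. Mpeg1, whose only peak was lowered, is not on that list. A different share of other cells in the 2 genotypes was not tested. The miR-155 host gene list had no peak.

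The lowered peaks held only part of the AGO2 reads of most of their genes. In the 79 genes with a lowered peak, these peaks held a median of 33.4% of the gene's wild-type reads (quartiles 20.6 and 76.0%). Summed over all peaks, these genes had a median log2 ratio of 1.00, against 0.06 for genes without a lowered peak. The sums include the lowered peaks by which these genes were chosen, so that choice raises their ratio. Tnfsf9 lost most of its AGO2 reads, from 519 to 39.1, and Lpin1 went from 1003 to 210. Hif1a, in contrast, had 4285 and 4747 in total, and Cd69 3320 and 3482. The 5 genes with 2 lowered peaks each were Arhgap18, P2ry10, Rc3h2, Rcor1 and Slc38a2. These sums rest on pooled reads and have no test.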

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

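The thresholds and the minimum of 10 scaled reads for calls of peaks, that minimum, the missing pseudocount, the site definitions and the widened region for miR-155 site peaks, and the lists without known targets were set beforehand. The other alternatives, including all of those for miR-181 and miR-29 and the other calls for gene lists, were chosen after seeing the data. The 84 lowered peaks became 67 at an adjusted p below 0.01, 96 below 0.1 and 93 with at least 10 scaled reads, and 49 with Bonferroni adjustment and 39 with peaks that had reads in both genotypes; the last leaves out 43 of the 84 by construction. Their genes, 79, became 46 and 37 in those last 2 settings. The 4 raised peaks became 2 below 0.01, 13 below 0.1, 10 with at least 10 scaled reads, 1 with Bonferroni adjustment and 1 with reads in both genotypes, so their number is uncertain; the last setting leaves out 3 of the 4 by construction. The share of lowered peaks with a 7-nt or 8-nt site lay between 64.1% and 77.6% over the other sets of calls, and every site definition kept Fisher's exact test past 0.05. The median log2 ratio of site peaks stayed above the matched range in all 11 alternatives, up to 3.66 for 8mers. The lowest were 1.58 over the 107 site peaks with reads in both genotypes and 1.82 over the same peaks with no pseudocount; both leave out every peak listed at 0. The miR-181 lean stayed outside its matched range among peaks with reads in both genotypes. With at least 17.6 scaled reads it lay at the edge of that range, just outside (-0.1412, range -0.1403 to 0.1773). With at least 10 scaled reads it lay inside (-0.07). The miR-29 lean lay inside it among peaks with reads in both genotypes, with the pseudocount (-0.06) and without it (-0.06). Known targets with a lowered peak, 12, became 7 with reads in both genotypes. By Fisher's exact test 1 list passed the threshold, the known targets; without those genes 0 of 13 lists passed. By medians against matched sets 1 list passed, the known targets. Without those genes 3 passed, all toward the knockout (cytokine receptors, helper T cell transcription factors and apoptosis, the last turned by leaving out Trp53inp1 alone). These sets took peaks of the same gene as separate, so their p-values may be too small. With other calls 2 lists passed Fisher's exact test each time. PI3K-AKT-mTOR was the added list below 0.01 (adjusted p = 0.0463) and with Bonferroni adjustment (0.0223). Ubiquitin ligases were the added list below 0.1 (0.00886), with at least 10 scaled reads (0.00781) and with reads in both genotypes (0.00947). Both lists share genes with the known targets. At the main calls without those genes, 1 of 15 PI3K-AKT-mTOR genes and 2 of 13 ubiquitin ligases had a lowered peak. The other calls were not tried without known targets, and the cause was not tested. Of the 28 peaks named by p or as known targets, 3 lost their call below 0.01 and 4 with Bonferroni adjustment.

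No paired analysis was possible because the deposited table pools the libraries of each genotype, although the labels share replicate numbers. For the same reason the alternatives set beforehand on normalization, filters and tools, the linker term, library letters, each linker alone, single or shallow libraries left out, set tests with estimated correlation, the comparison of linkers, its interaction with genotype, and changes of a peak relative to its gene were not run. No peak under 17.6 scaled reads was called; how few reads the authors' test needs for a call is unknown.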

Other observations

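The tests of 1-mismatch sites, of chance calls and of matches within 100 nt were chosen after the results were seen, as were the values on microRNA genes, top genes, site position and the reverse complement. The tests within site classes were not among those set beforehand. The other tests below were set before their results were seen, except where stated.

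The most-read AGO2 peak of the table lay on a microRNA gene. Peak 2 of Vmp1 (chromosome 11, 86584105 to 86584146 of GRCm38) held 16775 scaled reads in wild type and 20008 in the knockout, 4.94% of all reads, and overlapped Mir21a, the gene of miR-21, annotated within this 3' UTR. Peak 3 of Vmp1 overlapped it too, with 1003 and 2325 reads. Both peaks of Dvl2 overlapped Mir324, with 914 and 1713 reads at peak 1. In all, 11 peaks with 5.91% of the reads overlapped annotated microRNA genes on the same strand, and none was called different between genotypes. Reads over these genes can be the microRNA carried by AGO2, not a target, so the Vmp1 and Dvl2 totals are not read as targeting here.

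Among the 42 genes in the top percent by reads, 32 had more AGO2 reads in the knockout, Vmp1 and Dvl2 among them. The median log2 ratio of the 42 was -0.17, against 0.07 over all 2956 genes with at least 17.6 scaled reads. Satb1, a chromatin organiser of T cells, had 1389 scaled reads in wild type and 2479 in the knockout, Il2ra had 1934 and 3293, and Irf4 had 1232 and 1849. Myb, a transcription factor gene of progenitors, went the other way with 1753 and 1111, and Trp53inp1 had 1703 and 1048. No peak of Satb1, Il2ra, Irf4, Myb or Trp53inp1 was called, and these sums have no test. The miR-155 site of lowered peaks lay a median of 2.5 nt from the middle of the sequence, against 6.5 nt in other site peaks. The median share of A and U was 68.0% in lowered peaks, 63.5% in sets matched on reads but not on the site, and 66.7% in site peaks that were not lowered.

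A first pattern is that 16 peaks lowered in the knockout have neither a 6mer nor an offset 6mer, Hif1a, Wnk1 and Arhgap18 among them. A 7-nt or 8-nt match outside the deposited sequence was present within 50 nt in 2 of the 16 (12.5%, exact 95% interval 1.55 to 38.3%), the range set beforehand. That range was too narrow, since within 100 nt it was present in 5 of the 16 (31.2%, interval 11.0 to 58.7%) against 164 of 6684 other peaks. Peak 2 of Arhgap18 and peak 15 of Slc38a2 lie within 100 nt of a lowered peak with an 8-nt site. Neighbouring sites therefore stay open. In the opposite direction 4 peaks without a match were called (2-sided exact binomial test, p = 0.0118). The calls were 9 and 1 with reads in both genotypes (p = 0.0215), 9 and 2 at an adjusted p below 0.01 (p = 0.0654) and 6 and 1 with Bonferroni adjustment (p = 0.125). They were 20 and 10 with at least 10 scaled reads (p = 0.0987), 22 and 13 at an adjusted p below 0.1 (p = 0.175), and 55 and 46 at an unadjusted p below 0.01 (p = 0.426). Chance as the cause of the whole set is argued against, since 6 of the 16 pass Bonferroni adjustment, where uniform p-values would give 0.048 (Poisson p = 1.63e-11). This rests on the authors' p-values, whose distribution was not uniform and whose test is not known. How many of the other calls are chance stays open. Sites with 1 mismatch to the seed were present in 8 of the 16, against a median of 2 and a 95% range of 0 to 5 in random peaks matched on reads and length, so imperfect pairing may account for part of the set. A wider set was the 55 peaks without a match that were higher in wild type at an unadjusted p below 0.01. There GCTTTAA had the smallest p of 33 variants (7 of the 55, Fisher's exact test, adjusted p = 5.99e-05). This set contains the 16, and 4 of its GCTTTAA peaks are among them, so it is not separate evidence. In the same set none of 4085 6-mers passed adjustment. What holds the peaks without such a site, Unc119b and Trib1 among them, stays open.

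A feature that overlaps the 1-mismatch sites is given as values. Of the 16, 4 (Hif1a, Wnk1, Fbxo11 and Hiat1) contain the reverse complement of a 7-nt site, against 105 of 6877 other peaks without these matches (Fisher's exact test, p = 9.30e-05). In all 4 it shares bases with a 1-mismatch site. They are among the 8 peaks counted above for such sites, so this is not separate evidence. The 192 peaks with that sequence and without these matches had a median log2 ratio of 0.10, against 0.15 in matched sets.

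A second pattern is that peaks with few reads lean toward wild type: the median log2 ratio was 0.69 below the median of reads and 0.02 above it. Whether extra noise in the knockout accounts for it could not be told. The summed wild-type reads of the 7317 low peaks were 1.42 times those of the knockout (bootstrap 95% interval 1.37 to 1.47). Above the median they were 0.961 times. The peaks were split by the reads of both genotypes together, so noisier knockout reads could by themselves give such ratios. miR-155 sites do not account for it, since the 6899 low peaks without a 6-nt match kept a median of 0.63. How peaks were called and scaled was not tested, so selection of peaks with more wild-type reads stays open, and so does the genotype itself.

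The last pattern is that the other peaks of genes with a lowered peak also lean toward wild type. Peaks with a 6mer, an offset 6mer or a longer match were left out here, in these genes and in the matched ones. The median log2 ratio was 0.33 over 67 genes, against -0.01 in genes matched on reads. Reads of the lowered peak reaching its neighbours are argued against as the whole cause, since the lean was 0.23 without peaks within 100 nt (95% range of matched genes -0.13 to 0.14). Weak sites within the deposited sequences are likewise argued against as the whole cause. The lean was 0.26 once peaks with a 6mer-A1 or 1-mismatch site were left out too (range -0.15 to 0.11). Sites outside the deposited sequences were not searched here, and this exclusion was not combined with that of peaks within 100 nt. Sites missed in that way therefore stay open. A lower level of AGO2 on the whole transcript in the knockout stays open as a biological hypothesis, as does a technical source in the calling of peaks; RNA levels were not used here.

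A hypothesis on the site peaks that kept reads is that another microRNA holds AGO2 there. The 25 site peaks that also held a site of another family had a median log2 ratio of 1.22, against 3.91 for the 118 without, a difference of -2.68 (2-sided permutation test, p = 0.00038). This is consistent with the hypothesis for part of these peaks. Of the 11 at or below 0, 5 held such a site, Chd7 and Map3k8 among them, and 6 held none, against 20 with one among the other 132 (Fisher's exact test, chosen after the values were seen, p = 0.0243). Within site classes the difference was -2.72 for 7mer-m8 (14 against 33 peaks, permutation p = 0.0014), -1.45 for 8mer (4 against 33, permutation p = 0.298) and -1.36 for 7mer-A1 (7 against 52, permutation p = 0.184). Sequences with another site were longer, by a median of 53 against 51 nt in all. The medians were 52 against 49 nt for 7mer-m8, 69.5 against 48 for 8mer and 67 against 52 for 7mer-A1. Peaks were not matched on length, so a part of length in the difference was not tested.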
